A study of Mus musculus with 4 samples.

How the data were processed

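DamID was performed in AML12 cells treated for 5 days with 8 μM UNC0638 or with DMSO. Cells expressed Dam-LaminB1 or Dam alone from a lentivirus for 48 hours before harvest, per the labels' protocols. Methylated DNA was cut with DpnI, ligated to adapters, cut with DpnII and amplified, and the 2 materials of each sample were labelled with different dyes. The table holds 1 column per array, and its features are named by number. Every column was matched to a sample by its accession.

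The authors deposited 1 log ratio per feature and array. The submitters' processing notes name Agilent Feature Extraction; its version, the normalization within each array and the log base are not given in the sources used here. The deposited column medians were 0, 0, 0.00066 and 0.0090 for DMSO replicates 1 and 2 and UNC0638 replicates 1 and 2, and values ranged from -2.37 to 3.16. The direction of the ratio is likewise unstated and was taken as Cy5 over Cy3 from the labels. All arrays correlate positively with each other, so they run the same way; if the true direction were the opposite, every higher would read lower. A log ratio does not show which of the 2 materials changed. Channel intensities were not used here, so brightness, saturation and background could not be examined, and precision is limited by the number of arrays.

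An exact 0 was the value of 40425 features on DMSO replicate 1, 4371 on DMSO replicate 2, 3944 on UNC0638 replicate 1 and 25864 on UNC0638 replicate 2, while no other value occurred more than 2 times on any array. These zeros were read as ratios that were not estimated. The 54912 features at 0 on at least 1 array (5.64%), among them 1530 at 0 on all 4, were left out, and 919104 features were kept. This filter was chosen after the zeros were seen, and the fit on all features was run as an alternative. Control spots cannot be told from the feature number, so those with an estimated ratio remain in the table.

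Before the data were examined, tests were planned per gene (at least 3 probes), per window of 100 kb, per gene list and per single probe. Features carry no gene name or position here, so only the test of single probes was run, and the ranking and sign comparisons planned for genes were made on features. No gene list was tested. The rule for named items, also fixed before, was in that case the 2 features with the largest rise and the 2 with the largest fall in group mean.

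Each array was centred on its median. UNC0638 was compared with DMSO by a linear model per feature with empirical Bayes moderation in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, using all 4 arrays and no covariates. The test was tried on simulated data with the real features' means and noise drawn from the fitted model, independent and equal on all arrays. In limma's test, 5.02% of unchanged features had an unadjusted p under 0.05. Since the noise followed the model's own form, that rate does not show that the test is calibrated on the real arrays. Sign changes were counted with no margin, as planned, and with a margin of 0.25, which was planned as an alternative and made a comparison of its own after the data were seen, and the same counts were made for the 2 other ways to split the 4 arrays into pairs. The recurrence of differences between disjoint pairs of arrays was added after the data were seen. For the contrast between lamina-rich and lamina-poor features, the top and bottom 25% on 1 DMSO array were compared on the others.

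Alternatives planned beforehand were, for the test of single features, the values as deposited, quantile normalization, the replicate number as a block and each array left out in turn. For the contrast they were classes of 10% in the place of 25%, scaling to equal median absolute deviation and each array in turn for ranking, and for crossings with no margin and shares above 0 the values as deposited. Added after the data were seen were quantile normalization, that scaling, the values as deposited and the omission of arrays for the other results, the fit on all features, trended and robust moderation, a margin of 0.5, and the subtraction of the median of each block of 12 by 12 neighbouring features. The last assumes an array of 1068 rows by 912 columns. It rests on the correlation between a feature and the one 912 places further on, which was the highest among distances of 900 to 924 for the difference between groups (r = 0.020).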

Results

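Lamina contacts were mapped by DamID in AML12 cells, a mouse hepatocyte line, grown with UNC0638 or with DMSO as the vehicle control. UNC0638 inhibits G9a and GLP, histone methyltransferases that place repressive methylation on histone H3. In DamID a bacterial adenine methyltransferase (Dam) is fused to a protein of interest, here Lamin B1 of the nuclear lamina, and DNA that touches the lamina in living cells becomes methylated. Dam alone, expressed in parallel cells, marks DNA that is merely accessible and serves as the reference. Methylated fragments were amplified and hybridised to 2-colour Agilent arrays, 2 per group and 4 in all, of which 919104 features were compared. On each array the Dam-LaminB1 material carried Cy5 and the Dam-only material Cy3, with no dye swap.

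A positive log ratio most likely means more Dam-LaminB1 than Dam-only signal, that is, lamina-rich DNA. This direction rests on the dyes in the labels and on Agilent's usual order of red over green. The log base is not given in the sources used here: a difference of 1 unit is 10-fold if the base is 10 and 2-fold if it is 2, so differences are given in deposited log units and not as fold changes. Features are known here by number only. No gene, region or gene group could be named, and all statements below concern numbered features. Nothing in the labels says that the replicates came from separate cultures, so each p measures only the spread between these samples. The number of arrays limits the precision of every value.

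The first question was where Lamin B1 contacts lay in each group. All 4 arrays showed a broad distribution of log ratios with a sharp peak at 0.05 to 0.15 above the median and a shoulder or second peak of lamina-poor features below it. The lamina-poor mode was a local maximum at -0.75 in UNC0638 replicate 1 and at -0.65 in UNC0638 replicate 2, while DMSO replicate 2 had no separate maximum there. DMSO replicate 1 had only a slight one at -0.45. That bin held 4.41% of features, against 4.38% at -0.35 and 4.49% at -0.25, so it is better read as a shoulder. The standard deviation over the 919104 features kept was 0.753 and 0.789 on the DMSO arrays and 0.773 and 0.821 on the UNC0638 arrays. Features above the array median on both DMSO arrays made up 40.5% of those kept, and features above it on both UNC0638 arrays 42.4%. The shares below the median on both arrays were the same, 40.5% and 42.4%. Centring fixes the share above the median on each array. These values therefore measure how well the 2 arrays of a group agreed, and not the amount of lamina contact. Across all 4 arrays, 32.8% of features were always above the median and 34.1% always below it.

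**Figure D1:**
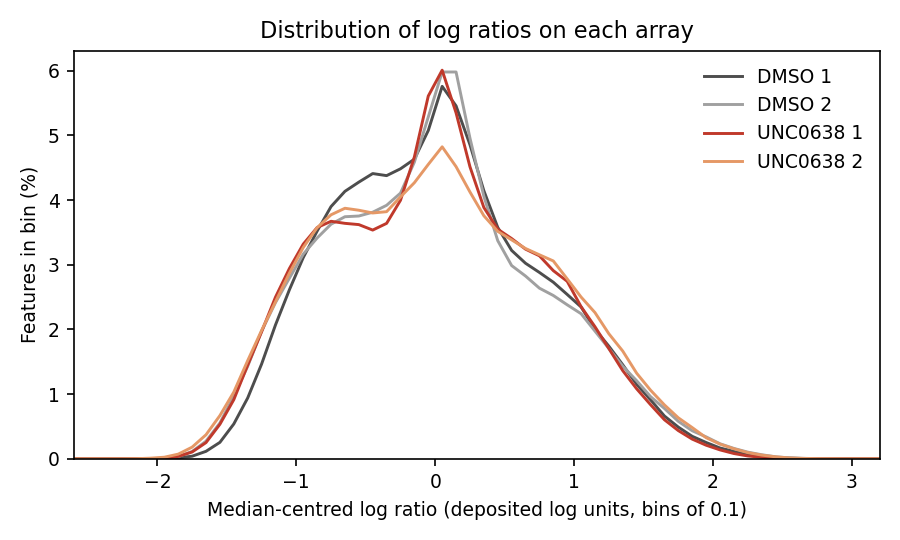
Distribution of median-centred log ratios (x axis, deposited log units, bins of 0.1) as the percent of the 919104 features in each bin (y axis), 1 line per array, DMSO in greys and UNC0638 in red and orange. All arrays peak just above 0, and the upper tails reach further than the lower ones.

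The overall map of lamina contacts was shared between groups. Across features, Pearson's r between a DMSO and a UNC0638 array ranged from 0.809 to 0.821, which includes no value below the r of 0.798 between the 2 DMSO arrays. The 2 UNC0638 arrays agreed best, at r = 0.871. Spearman's rho gave the same order, with 0.786 within DMSO, 0.799 to 0.810 between groups and 0.866 within UNC0638. Features are not independent replicates, so these correlations describe the arrays and carry no p-value. By root mean square difference the order was mixed, with 0.492 within DMSO, 0.468 to 0.497 between groups and 0.408 within UNC0638.

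The central comparison asked which features changed their lamina association after 5 days in 8 μM UNC0638. No single feature passed limma's moderated test at an adjusted p of 0.05 (Benjamini-Hochberg over 919104 features), and the smallest adjusted p was 0.531. At an unadjusted p under 0.05 there were 73458 features, 7.99% of those tested, of which 43157 were higher and 30301 lower in UNC0638. The same fit was made on the 2 other ways of pairing the 4 arrays. It gave 36591 features (18643 higher, 17948 lower in the pair holding DMSO replicate 2) and 41619 (17080 higher, 24539 lower). Both directions were thus more frequent between UNC0638 and DMSO, and an imbalance between directions also arose in another pairing. Each other pairing puts 1 array of each group on both sides. A group difference would therefore add to its noise and lower its count. With 1 array left out, the comparison of UNC0638 with DMSO gave 96487 without DMSO replicate 1, 96508 without DMSO replicate 2, 50210 without UNC0638 replicate 1 and 41311 without UNC0638 replicate 2. Fits on 3 arrays were not made for the other pairings, so these counts have no such level beside them. In each fit with 1 array left out, the spread comes from the group that kept 2 arrays. The count rose above that of all 4 arrays when this group was UNC0638, and fell below it when it was DMSO. The count thus depends on which group sets the spread. Arrays of the same size were simulated with noise drawn from the fitted model, equal in both groups. With 5% of features shifted, the fit called 72.9% of features shifted by 2 units but only 2.80% of those shifted by 1 unit. With 200 shifted features it called none, even at 2 units. Under this simulated noise, a set of 200 features shifted by up to 2 units was therefore not detectable one by one with 2 arrays per group. Sets of sizes other than these, or larger shifts, were not simulated.

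The largest differences were of about 2 units. Feature 414413 rose from -0.93 ± 0.03 in DMSO to 1.49 ± 0.45 in UNC0638 (SD, n = 2 each), a difference of 2.42 with a standard error of 0.27. Feature 648987 went from -0.67 ± 0.0015 to 1.65 ± 0.09, a difference of 2.32. In the other direction, feature 88375 had 1.37 ± 0.28 in DMSO and -0.79 ± 0.60 in UNC0638, and feature 12816 had 1.41 ± 0.26 and -0.57 ± 0.01. All 4 had an adjusted p of 0.531 in limma's test, so none of them is called changed. Over all features the middle of the distribution lay slightly below 0, with a median difference of -0.03, whereas the upper tail was longer than the lower. The 99.9th percentile of the difference was 1.43 and the 0.1th percentile -1.24. Both UNC0638 arrays lay above both DMSO arrays for 17.3% of features and below both for 21.7%, where chance alone gives 16.7% each way. The 2 other pairings gave 15.6% and 14.5%, and 13.7% and 17.2%, so an imbalance between directions also arose without a treatment difference. A feature whose arrays lie apart in 1 pairing cannot lie apart in another. A difference between the groups would thus lower the shares of the other pairings.

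Features that crossed from below to above 0 were more frequent than the reverse once a margin around 0 was required. Here 0 is the median of each array, so a crossing is a change of rank about the median and calls no lamina state. With no margin, 21056 features were below 0 on both DMSO arrays and above 0 on both UNC0638 arrays, and 19378 went the other way, together 4.40% of features. The order of these 2 counts was not stable: it turned to 20433 upward and 21009 downward when features with an exact 0 were kept. The 2 other pairings of the arrays gave 12199 upward and 11752 downward crossings, and 13478 and 13241, with totals of 23951 and 26719. With no margin, both directions were thus more frequent between DMSO and UNC0638. The margin of 0.25 had been set beforehand as an alternative only, and was taken up as a comparison of its own after the data were seen. When a feature had to lie more than 0.25 from 0 on every array, 2894 features (0.31% of those kept) crossed upward in UNC0638. Downward crossings numbered 824 (0.090%), a ratio of 3.51. With any 1 array left out, which loosens the criterion, the ratio was lower: 2.18 without DMSO replicate 1, 1.96 without DMSO replicate 2, 1.56 without UNC0638 replicate 1 and 1.92 without UNC0638 replicate 2. The upward and downward counts under the other pairings were 757 and 803, and 755 and 908. At a margin of 0.5, 328 features crossed upward and 48 downward, against 40 to 51 in either direction under the other pairings. At both margins upward crossings thus exceeded the counts of the 2 other pairings, while downward crossings lay within their range. Those counts are not an independent level without change. A feature with 2 arrays below 0 and 2 above is counted in only 1 pairing. A difference between the groups would thus take features away from the other pairings. These are counts without a p-value, since 4 arrays can be paired in only 3 ways and an exact test of 2 against 2 arrays cannot go below 0.333.

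**Figure D2:**
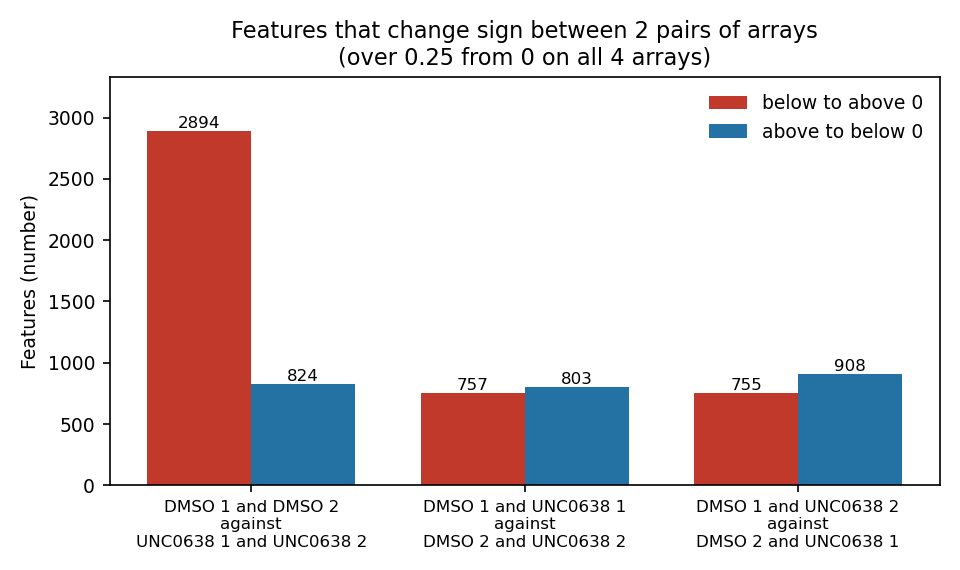
Number of features (y axis) whose log ratio lies more than 0.25 below 0 on both arrays of the first pair and more than 0.25 above 0 on both arrays of the second (red), or the reverse (blue), for each of the 3 ways to pair the 4 arrays (x axis). The comparison of DMSO with UNC0638 holds 2894 upward and 824 downward features, and the other pairings hold 755 to 908 in either direction.

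A difference seen in 1 pair of arrays recurred in the other pair more often for rises than for falls. Of the 22252 features that were more than 1 unit higher in UNC0638 replicate 1 than in DMSO replicate 1, 14.2% were also more than 1 unit higher in UNC0638 replicate 2 than in DMSO replicate 2. For the 21749 features that were more than 1 unit lower, the share was 5.99%. The contrast between replicates, which holds no treatment difference, gave 3.29% and 2.96%. It picks features between the 2 DMSO arrays and measures them between the 2 UNC0638 arrays. The UNC0638 arrays lay closer together, with a root mean square difference of 0.408, against 0.497 between DMSO replicate 2 and UNC0638 replicate 2. Fewer features can then pass 1 unit by noise alone, so the shares for rises and falls are set against a low level. Features picked as crossing upward by the margin in the replicate 1 arrays had a mean of 0.04 in DMSO replicate 2 and 0.27 in UNC0638 replicate 2, a mean difference of 0.23. Those picked as crossing downward had means of -0.10 and -0.11. With the DMSO arrays exchanged, the mean difference was 0.24 for features picked as crossing upward and -0.05 for those picked as crossing downward. Features picked in the same way between the 2 DMSO arrays differed between the UNC0638 arrays by 0.01 when picked upward and by 0.03 when picked downward. Across all features, the difference in the 2 disjoint pairs of arrays correlated weakly, at Pearson r = 0.114 and Spearman rho = 0.105, against -0.018 and -0.016 for the contrast between replicates.

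The last comparison asked whether the contrast between lamina-rich and lamina-poor DNA was larger or smaller after inhibition. Features were ranked on 1 DMSO array and measured on the other arrays, so that the noise of the ranking array did not enter the values. With ranking on DMSO replicate 1, the top 25% exceeded the bottom 25% by 1.61 in DMSO replicate 2 and by 1.61 and 1.71 in the UNC0638 arrays. With ranking on DMSO replicate 2, the values were 1.54 in DMSO replicate 1 and 1.63 and 1.72 in the UNC0638 arrays. The mean change was 0.096, against a standard deviation of 0.063 between the 2 UNC0638 arrays. It was 0.039 after quantile normalization and -0.038 after scaling to equal median absolute deviation. With ranking on a UNC0638 array it was 0.235 or 0.136. Those values set the other UNC0638 array against the DMSO arrays, so the closer agreement of the 2 UNC0638 arrays raises them and they are not like alternatives. The direction of the change thus differed between 2 ways of giving the arrays equal spread, and no change in contrast is called. In the lowest 10% of features the mean difference, UNC0638 minus DMSO, was -0.038 or -0.124, depending on which DMSO array served for ranking. It was 0.049 or 0.054 in the 10% next to the highest. In the highest 10% it was -0.0024 or 0.039, with 0.013 or 0.019 after quantile normalization and -0.085 or -0.078 after scaling to equal median absolute deviation.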

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

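Fits on all features, with trended moderation or with block medians, the margin of 0.5 and crossed pairs were chosen after the data were seen, as were arrays left out and quantile normalization beyond the test of single features. No feature passed the adjusted threshold in any of the 11 alternative fits, whose smallest adjusted p ranged from 0.411 to 1.00 (limma). The number at an unadjusted p under 0.05 stayed within 1.5 times the reported 73458 except without UNC0638 replicate 2, where it was 41311, and reached 96508 without DMSO replicate 2. That fit assumes that a lone array varies like the other group's. With the replicate number as a block it was 67924. The deviations of same-numbered arrays correlated at -0.018, so the numbers were not taken to pair the arrays, and the replicate block changed no call. The 4 named features kept their direction throughout, which follows from picking them for the largest differences on these same arrays. Upward crossings fell from 21056 to 2894 and downward ones from 19378 to 824 when the margin of 0.25 was set, and to 328 and 48 at 0.5. Leaving out an array loosens the criterion by construction: upward crossings then ranged from 39052 to 54697 and downward ones from 44191 to 48117 with no margin, and from 6873 to 11824 and 3574 to 6012 with the margin of 0.25. The excess of upward over downward crossings at that margin was then 1.56 to 2.18, lowest without UNC0638 replicate 1, against 3.51 with all arrays. With no margin, downward crossings outnumbered upward ones without UNC0638 replicate 1 or 2 and with exact zeros kept (21009 against 20433). The contrast between lamina-rich and lamina-poor features turned from 0.096 to -0.038 under scaling to equal median absolute deviation but was 0.039 after quantile normalization, and was 0.235 with ranking on UNC0638 replicate 1; without UNC0638 replicate 1 it was 0.141 and without replicate 2 it was 0.051. The change with ranking on a DMSO array needs both DMSO arrays and could not be computed without 1 of them. With ranking on UNC0638 replicate 1, the contrast was 1.85 in UNC0638 replicate 2. It was 1.57 in DMSO replicate 1 and 1.66 in DMSO replicate 2, so the size of that change depends on the DMSO array used. Shares above 0 on both arrays were 41.6% (DMSO) and 43.5% (UNC0638) in the values as deposited and 40.4% and 42.2% after block medians were subtracted. The correlation of differences in disjoint pairs was 0.131 with the pairs crossed and 0.099 under equal scaling. The cause of these shifts was not tested. The settings set out for genes, windows and gene lists, array weights among them, were not run.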

Other observations

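Both UNC0638 arrays lay below both DMSO arrays for 21.7% of features and above them for 17.3%, but another pairing (DMSO replicate 1 and UNC0638 replicate 2 against the others) gave 17.2% and 13.7%. Differences of more than 1.5 units present in both disjoint pairs of arrays numbered 216 upward and 39 downward. The corresponding counts for the contrast between replicates, which is measured in part between the closer UNC0638 arrays, were 26 and 31. The covariance across features averaged 0.499 between groups, and was 0.474 within DMSO and 0.553 within UNC0638. Only the value within UNC0638 exceeded that between groups. These values therefore cannot tell a component that separates the groups from closer agreement of the 2 UNC0638 arrays alone.

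The test of a local flaw was set down before its result was seen, and all other tests in this part were chosen after. Those on neighbouring features took the place of subtracting block medians, which had been set down before but rests on an assumed layout and moved the counts little (to 73229 features at an unadjusted p under 0.05 and 2636 upward crossings).

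The first pattern is that UNC0638 against DMSO gave more features at an unadjusted p under 0.05 than the other pairings did. Of the 3 pairings, 1 (the real one, with 73458) reached that number and the highest other had 41619, which is too few splits for a share under 0.05. Unequal spread of values over the features of an array does not explain it, as quantile normalization left 73659 against 42125. That step does not equalize noise within the pairs, whose root mean square difference was 0.408 in UNC0638 and 0.492 in DMSO. It therefore does not bear on unequal noise between the groups. The other pairings are also no level without change, as a group difference would lower their counts. A shift shared by neighbouring features does not explain the pattern either. The difference in 1 pair of arrays had a covariance of -0.00090 with that of the next feature number in the other pair. Independent noise of single arrays would give the difference in disjoint pairs of arrays no covariance, and it was 0.0265 against -0.0036 for the contrast between replicates; this test took the place of a weaker one, which bore on noise in DMSO replicate 1 alone. A treatment effect and a step shared by the UNC0638 arrays, which agreed at r = 0.871, cannot be told apart, because the labels give no batch.

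The second pattern is the excess of upward over downward crossings at a margin of 0.25, a margin taken up as a comparison after the data were seen. It was not removed by quantile normalization (2820 upward, highest other count 884). The values as deposited gave 2902 against 1074. Their medians over the features kept lay between -0.0019 and 0.039, close to 0 beside the margin of 0.25. That setting moves 0 too little to test whether the excess depends on where 0 is placed. Features numbered next to the upward ones exceeded the mean difference of all features by 0.00065 (standard error 0.0048), which argues against a shift shared by neighbours. Under the assumed layout, 15.0% of the upward features lay in the 10 fullest of 100 areas, against 10.3% of all features, which argues against a local flaw as the whole source. The areas were picked as the fullest for these same features, and few features give uneven counts even without a flaw. The 10.3% is thus not the level to expect, and a flaw behind part of the crossings could not be examined. An effect of UNC0638 stays open as an untested hypothesis, since the ratio of 3.51 cannot be told apart from shared processing of the UNC0638 arrays and the labels give no batch.

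Exact zeros set apart 1 array of each group. DMSO replicate 1 had 4.15% of features at 0 and UNC0638 replicate 2 had 2.66%, against 0.449% and 0.405% on the others. The pairing that follows this division, DMSO replicate 1 and UNC0638 replicate 2 against the others, gave 41619 features at an unadjusted p under 0.05 and 755 upward and 908 downward crossings at the margin, where the real grouping gave 73458, 2894 and 824. Features at 0 on DMSO replicate 1 alone had a standard deviation of 0.473 on UNC0638 replicate 1, against 0.773 for the features kept.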
